A study of Homo sapiens with 22 samples.

How the data were processed

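RNA of A549 cells exposed to adipocyte exosomes at 10 doses, and of control cells without exosomes, was labelled as biotin cRNA and hybridised to Illumina HumanHT-12 bead arrays, 22 in all. Per the labels, the authors used GenomeStudio and Partek, and neither the versions nor the order of the steps are stated. Each deposited table holds 1 bead intensity and 1 detection p-value per probe and array. The intensity values in both deposited tables are on a linear scale with the background not subtracted, and the detection p-value, per the file headers, sets each probe against the array's negative control beads. The table that the authors named non-normalized was already quantile normalised: its 20 exposed arrays share a distribution, with medians from 75.1286 to 75.1515. In the table that the authors named normalized, every array was scaled to a mean of 172.198, with medians from 68.9 to 94.2, and the series matrix holds the same values (largest difference 0).

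The control columns of the quantile normalised table stand apart from the exposed ones. Their spread at background was 2.71% of the median, against a median of 3.42% for exposed arrays, and their probes were ordered differently from the other table at 22054 and 21856 places, against 15 to 64 for exposed arrays. The labels do not say how they were made. If they are means of several arrays, control values vary less than exposed ones, and the pooled spread is only approximate for comparisons with the control.

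Values of the quantile normalised table were background corrected with the detection p-values, quantile normalised again and put on the log2 scale with neqc of limma 3.58.1 (offset 16) in R 4.3.3. Of 47307 probes, 30105 had 1 gene symbol in the platform table, 8 had several and 17194 none, and 30066 of the named probes matched a current gene through their Entrez ID. A probe was kept when detected at p under 0.01 on at least 2 arrays, which left 15024 named probes. Each gene was taken as its probe with the highest mean, giving 11330 genes, and 4821 unnamed probes were set aside. From 14289 to 17666 probes were detected per array, and the correlation between arrays across genes lay between 0.968 and 0.997. Where a gene was undetected in a group, its fold was computed against the lowest signal of a detected probe on the same arrays, or its own signal if higher, and is given as at least that fold.

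Genes were tested with limma (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). The comparisons were the slope on log2 dose over the 20 exposed arrays, all exposed arrays against the 2 controls, dose 10 against control with the spread pooled over all 11 groups, any dose against control by a moderated F test, series 2 against series 1 with the dose as a block, and the difference of the slopes between the series. These comparisons and the gene lists were fixed before the data were examined, as were the alternatives except those named below as later ones. The series number pairs the arrays: over 55 pairs of groups, the differences between series 2 and series 1 correlated across genes with r from 0.108 to 0.503 (median 0.284), all 55 above 0.1. Fits with the series number as a block are therefore given beside the counts they moved. Apart from comparisons between the series, the SE and adjusted p of single genes come from fits without this block. At dose 10 the block raised the calls from 547 to 1061, so a gene that did not pass without it may pass with it. On simulated data of 11330 genes for the dose trend, 98% of 100 genes with a slope of 0.1 and 100% of 100 with a slope of 0.2 were recovered, all with the right sign, and 11 of 209 calls were false. The simulated genes were independent and had no series effect. Genes called on the real arrays had smaller slopes, with a median absolute slope of 0.042 in series 1 and 0.059 in series 2. These rates therefore do not carry over to the real data.

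Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists tested. Of 31 lists fixed beforehand, 28 had at least 3 measured genes. They hold 506 genes, of which 472 had a named probe and 361 were tested. Lists that share members, such as those with CLDN1, ATF3 or SLC7A11, are not independent. Named in the text are the 10 genes with the largest change in each direction among those past the threshold, the 5 with the smallest p where fewer than 5 passed, the 5 largest in each direction between the series, up to 4 genes of smallest p per list, and 9 genes of the study's question, of which 6 were tested. Members of a list beyond these 4, such as DDIT3, ASNS and NFKBIA in the dose trend, were chosen after their values were seen.

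Alternatives were other scalings and filters, other probes per gene, another variance model, other forms of the dose, each array left out in turn, and a block by series. Alternatives chosen after the data were seen were a background correction of the authors' normalized table, fits without dose 10 or with doses 1 to 6, the number of detected probes as a covariate, the lists at dose 10, doses 7 to 9 against control, and dose 10 against doses 8 and 9. Relations of array quality with dose, 9 in all, were tested by permutation. A block by chip could not be fitted, since the labels give no chip numbers.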

Results

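RNA of A549 cells, a line of alveolar epithelial cells from a human lung adenocarcinoma, was measured on 22 single-colour bead arrays after 24 hours with exosomes, small vesicles that cells release, from visceral adipocytes of obese donors. Per the labels, the exosomes were given at 10 doses (0.02, 0.04, 0.08, 0.16, 0.32, 0.64, 1.32, 2.64, 5.28 and 10.56 µg/ml, numbered 1 to 10), and control cells received none. The series description gives the top of the range as 10 µg without a volume, and the doses of the labels are used here. Each dose and the control had 2 arrays, numbered 1 and 2 in the labels and called series 1 and series 2 here. The labels do not say whether a series is a donor, a vesicle preparation, a culture or an array batch. The p-values of single genes below thus rest on the spread between these arrays, which can be technical. Those of camera for gene lists set the genes of a list against the other genes. Between 14289 and 17666 probes per array were detected, and 11330 genes were tested. The number of arrays limits the precision.

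**Figure D1:**
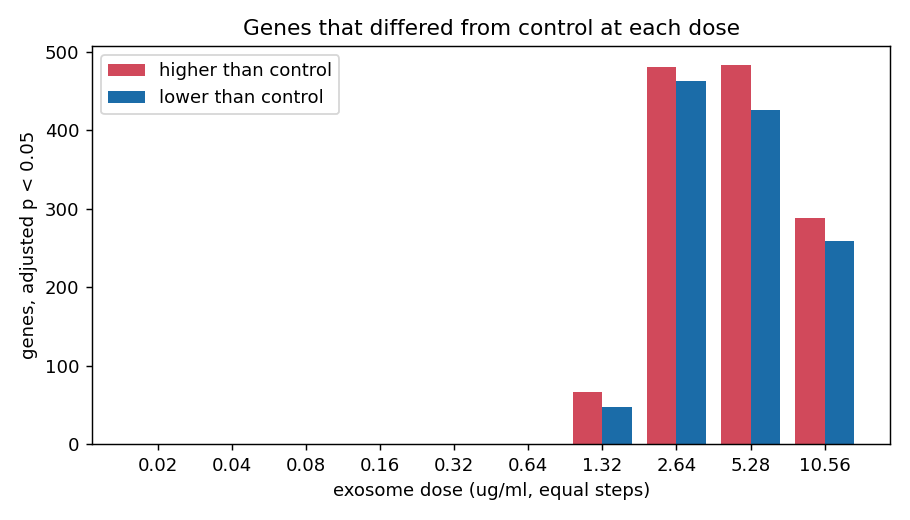
Number of genes that differed from the control at each exosome dose (x axis, µg/ml in equal steps; y axis, genes with an adjusted p under 0.05, higher in red and lower in blue). No gene passed at doses 1 to 6, and dose 8 had 480 higher and 462 lower genes.

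Each dose was compared with control cells. No gene passed at doses 1 to 6 in limma, which with 2 arrays per group sets no lowest active dose. At these doses 112, 70, 96, 89, 304 and 694 genes had an unadjusted p under 0.05. Only the last of these counts exceeded the number expected by chance at this cutoff if p-values are uniform without a response. The counts at the doses below dose 5 lay far under that number, so it is a poor yardstick for this fit. It therefore cannot decide whether the 304 genes at dose 5 hold a response. The median absolute log2 difference from control was 0.098 at dose 5, against 0.071 to 0.077 at the doses below it, untested. At dose 7, 66 genes were higher and 48 lower than in control cells, at dose 8, 480 and 462, and at dose 9, 483 and 425. With the series number as a block, 1 gene passed at dose 6, 558 at dose 7, 1664 at dose 8 and 1565 at dose 9. At dose 6 the list medians, untested, were already 0.30 and 0.72 for cholesterol synthesis and 0.44 and 0.65 for S phase in series 1 and 2. Each of these medians rests on 1 exposed array and the 1 control array of its own series. The gene counts at all doses rest on the same 2 control arrays.

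Across the 10 doses, the question was which genes follow the amount of exosomes. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 0.31 ± 0.06 log2 units per doubling of the dose (SE, 20 arrays, adjusted p = 0.000171). Its log2 signal was 5.73 ± 0.04 (SD, n = 2) in control cells and 9.17 ± 0.22 (SD, n = 2) at dose 10. TXNIP, which binds thioredoxin and restrains glucose uptake, fell by 0.35 ± 0.04 per doubling (SE, adjusted p = 2.47e-07). The largest fall was that of NIBAN1 at -0.39 ± 0.06 (SE). Its log2 signal was 9.08 ± 0.00 (SD, n = 2) in control cells and 5.81 ± 0.02 (SD, n = 2) at dose 9. NIBAN1 was not among the 10 genes with the largest falls past the threshold at dose 10. RAB17, a small GTPase, rose by 0.24, FGFBP1, which carries fibroblast growth factors, by 0.22, and FXYD2, a regulator of the sodium pump, by 0.21. From doses 8 and 9 to dose 10, RAB17 changed by 2.57 log2 units in series 2 and by -0.12 in series 1. KRT80 had a slope of -0.27, TNFRSF12A, the receptor of TWEAK, -0.24, DUSP5, an ERK phosphatase, -0.22, and BEX2 -0.21. BEX2 rose again from doses 8 and 9 to dose 10, by 2.67 log2 units in series 1 and 1.02 in series 2. A slope thus need not mean a steady change up to the top dose.

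The dose trend held for 3171 of the 11330 genes (adjusted p under 0.05), 1675 upward and 1496 downward, and for 3578 with the series number as a block (1880 and 1698). Fitted alone, series 1 gave 581 genes and series 2 gave 2798, and all of the 460 genes that passed in both had the same sign. With doses 1 to 6 alone, 0 genes passed in limma and 1227 had an unadjusted p under 0.05. The 28S ribosomal RNA probe also rose with the dose in series 2 (r = 0.841, rho = 0.855, permutation p = 0.00331, adjusted over 9 relations 0.0298, r = 0.810 without the 2 farthest arrays), against r = -0.230 in series 1 and 0.0329 over both.

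Genes of sterol and fatty acid synthesis rose with the dose. Of 14 measured cholesterol synthesis genes (targets of SREBP2), 13 rose and 1 did not pass, and the counts were the same when adjusted over the list alone. INSIG1, which retains SREBP in the endoplasmic reticulum, rose by 0.27 ± 0.04 per doubling (SE), and at dose 9 its signal was 4.66-fold that of control cells. MSMO1 rose by 0.25, HMGCS1, which makes HMG-CoA, by 0.22, LSS by 0.22, ACAT2 by 0.21 and DHCR7 by 0.17. HMGCS1 went from a log2 signal of 8.39 ± 0.04 (SD, n = 2) in control cells to 10.21 ± 0.01 (SD, n = 2) at dose 9. Of 11 fatty acid synthesis genes (targets of SREBP1), 9 rose, 9 when adjusted over the list alone, among them FASN at 0.18 ± 0.03 (SE), LPIN1 at 0.16, SCD at 0.14 and FADS2 at 0.10. The cholesterol list was called upward by camera with a preset correlation (adjusted p = 1.23e-12), with an adjusted p = 0.146 with an estimated correlation. The fatty acid list was called upward too (adjusted p = 1.13e-07), with an adjusted p = 0.139 with an estimated correlation.

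**Figure D2:**
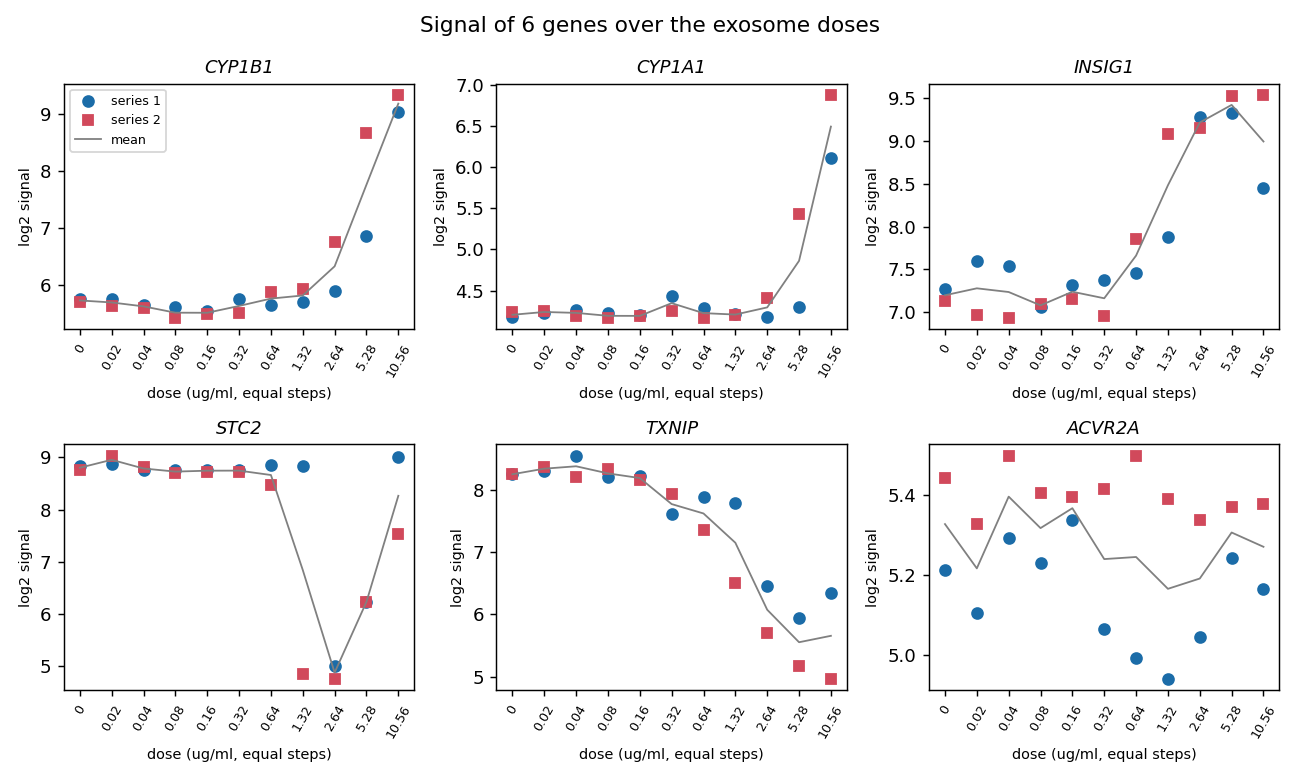
Log2 signal of CYP1B1, CYP1A1, INSIG1, STC2, TXNIP and ACVR2A (y axes, each with its own range) on each array of series 1 (circles) and series 2 (squares) over the control and the exosome doses (x axis, µg/ml in equal steps), with the mean of the 2 arrays as a line. STC2 in series 1 was at 5.00 at dose 8 and 9.00 at dose 10.

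Genes of the endoplasmic reticulum stress and amino acid response fell. Of 16 measured, 13 fell and 3 did not pass, and 15 fell when adjusted over the list alone. ATF3, a stress-induced transcription factor, had a slope of -0.27 ± 0.06 (SE), DDIT3, which encodes CHOP, -0.20, ASNS, asparagine synthetase, -0.19, PHGDH, the entry enzyme of serine synthesis, -0.18, and the chaperone HSPA5 -0.10. Outside the list, STC2 fell at -0.30 ± 0.08 (SE) and PCK2 at -0.25 ± 0.05 (SE). The list was called downward by camera with a preset correlation (adjusted p = 1.13e-07), with an adjusted p = 0.224 with an estimated correlation. A straight line describes it poorly at the top dose, where the list's median difference from the control of the same series went from -1.28 at dose 9 to 0.00 at dose 10 in series 1 and from -1.46 to -0.71 in series 2.

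Heat shock genes rose in 10 of 11 cases, 11 when adjusted over the list alone. HSPA1A had a slope of 0.23 ± 0.05 (SE), HSPA1B 0.18, HSPA8 0.15 and DNAJB1 0.11, and HSPA1A and HSPA1B differ too little in sequence for probes to be sure to separate them. The list was called upward with a preset correlation (adjusted p = 2.85e-07), with an adjusted p = 0.188 with an estimated correlation. Genes of S phase and DNA replication rose in 13 of 17 cases (adjusted over the list alone, 14 rose and 1 fell). MCM6, a subunit of the replicative helicase, rose by 0.18 ± 0.03 (SE), MCM5 by 0.14, PCNA by 0.11 and CCNE1, cyclin E, by 0.08. The S phase list was called upward with a preset correlation (adjusted p = 1.13e-07), with an adjusted p = 0.224 with an estimated correlation. Of 18 mitosis genes, CDK1 and KIF20A rose, 2 when adjusted over the list alone, and that list was not called (adjusted p = 0.385).

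**Figure D3:**
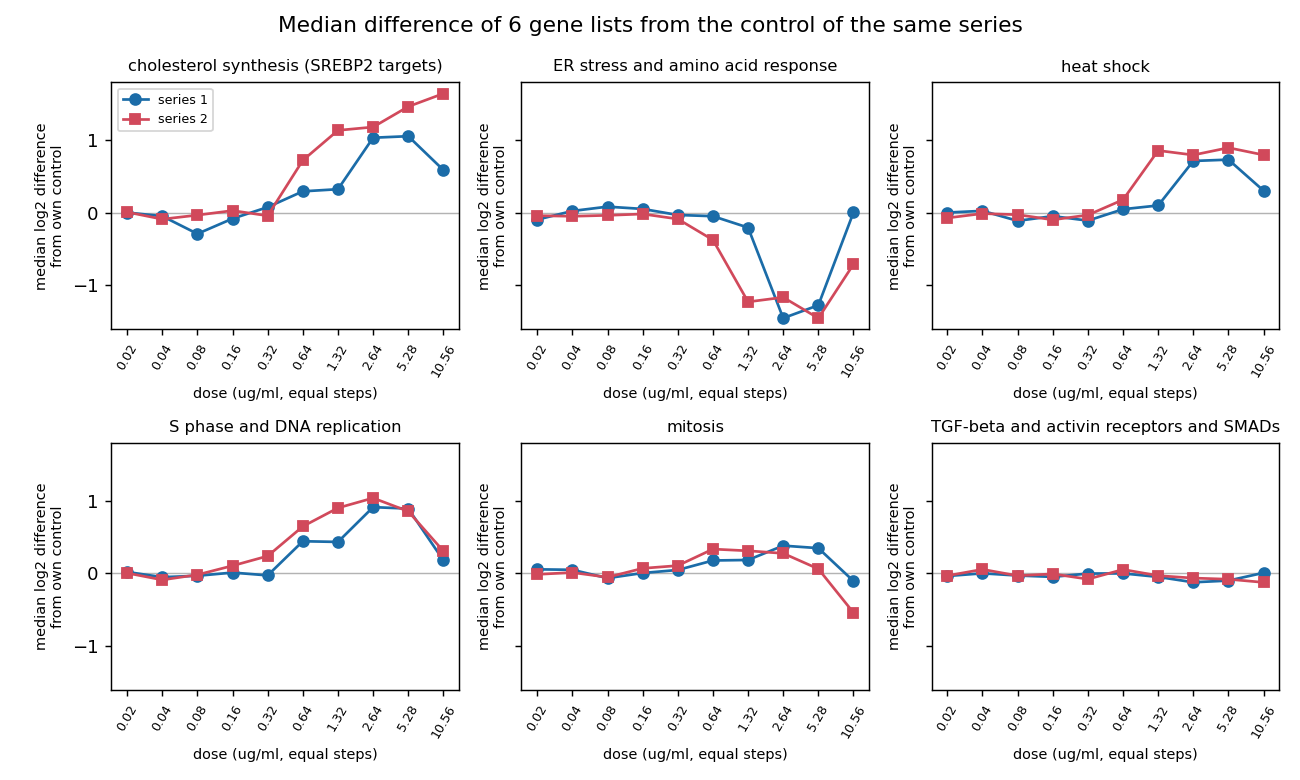
Median log2 difference of 6 gene lists from the control of the same series (y axis) over the exosome doses (x axis, µg/ml in equal steps) in series 1 (circles) and series 2 (squares). The cholesterol synthesis list reached 1.06 in series 1 and 1.46 in series 2 at dose 9.

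Genes of the NF-kappaB and cytokine list, the immediate early list and the TGF-beta target list fell more often than they rose. In the NF-kappaB and cytokine list, 7 of 15 genes fell and 3 rose (10 and 3 when adjusted over the list alone). The neutrophil chemokines CXCL8, CXCL5 and CXCL2 had slopes of -0.27 ± 0.04, -0.17 ± 0.02 and -0.16 ± 0.02 (SE), and the inhibitor NFKBIA rose by 0.10. Of 15 immediate early genes, 10 fell and 1 rose, the same when adjusted over the list alone. DUSP1, a MAP kinase phosphatase, had a slope of -0.19 ± 0.02 (SE), JUN -0.20 and DUSP6 -0.08. Of 18 TGF-beta target genes, 7 fell and 2 rose (7 and 3 when adjusted over the list alone). CCN2, a matricellular growth factor, had a slope of -0.18 ± 0.02 (SE), CCN1 -0.12, ID2 -0.07 and TAGLN -0.07. These lists were called downward with a preset correlation, the immediate early list with an adjusted p = 6.76e-05, the NF-kappaB list with 0.011 and the TGF-beta target list with 0.0226. In the same order, the adjusted p was 0.239, 0.163 and 0.224 with an estimated correlation.

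The study asked about TGF-beta and activin receptors and about Wnt and beta-catenin signalling. The activin receptor ACVR2B has 2 probes, which were detected on at most 1 array, and the probe of TGFBR1 was detected on 0, so neither could be tested. ACVR2A had a slope of -0.0083 ± 0.013 (SE, adjusted p = 0.68), TGFBR2 -0.019 ± 0.014 (SE, adjusted p = 0.367), SMAD3 -0.014 ± 0.012 (SE, adjusted p = 0.437) and SMAD7 0.00097 ± 0.011 (SE, adjusted p = 0.959). Of 17 genes of the receptor and SMAD list, TGFBR3, the co-receptor betaglycan, rose by 0.11 ± 0.02 (SE, adjusted p = 4.56e-05) and BMPR2 by 0.02, while SMAD4 and TGFB2 fell. The same 2 rises and 2 falls were counted when adjusted over the list alone, and the list was not called (adjusted p = 0.405).

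In the Wnt list, AXIN2, a feedback inhibitor and a target of beta-catenin, rose by 0.14 ± 0.01 (SE, adjusted p = 6.08e-08). Its log2 signal was 5.03 ± 0.02 (SD, n = 2) in control cells and 6.13 ± 0.13 (SD, n = 2) at dose 9. The co-receptor LRP5 and the receptor FZD5 rose by 0.05 each, and FZD8 had a slope of -0.08. CTNNB1, beta-catenin itself, had a slope of 0.012 ± 0.013 (SE, adjusted p = 0.536). Of 27 genes, 5 rose and 5 fell, 5 and 5 when adjusted over the list alone, and the list was not called (adjusted p = 0.832).

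Genes of vesicle handling, metal binding, oxidative defence and oxidative phosphorylation made up the other called lists. Of 15 genes of vesicle biogenesis and uptake, 8 rose, the same when adjusted over the list alone, with SDCBP, syntenin, at 0.10 ± 0.01 (SE), RAB27B, a GTPase of vesicle release, at 0.07 and CD9 at 0.06. Of 7 metallothionein list genes, 4 rose (5 adjusted over the list alone), with MT1X at 0.17 ± 0.02 (SE). The metallothioneins resemble each other closely, and the list also holds SLC30A1, which is not one of them. Of 17 NRF2 targets, 7 rose and 1 fell, the same when adjusted over the list alone, with HMOX1, heme oxygenase, at 0.17 ± 0.03 (SE) and the transporter ABCC2 at 0.08. Of 19 oxidative phosphorylation genes, 6 rose (8 adjusted over the list alone), with COX7B at 0.06 ± 0.01 (SE). The lists had adjusted p = 0.0105, 0.011, 0.0112 and 0.00497 with the preset correlation. With an estimated correlation, the adjusted p was 0.139, 0.239, 0.146 and 0.146.

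Among lists not called for the dose trend, hypoxia and glycolysis genes went both ways, with 7 of 18 up and 4 down (8 and 4 adjusted over the list alone, list adjusted p = 0.283). ENO1 rose by 0.07 and SLC2A3, a glucose transporter, had a slope of -0.10. Airway mucin and barrier genes were split as 4 up and 4 down of 14, the same adjusted over the list alone (list adjusted p = 0.958), with MUC1 up by 0.12 and CLDN1 at -0.12. PPAR targets had 3 up and 1 down of 11, the same adjusted over the list alone (list adjusted p = 0.283), p53 targets 2 up and 4 down of 14, the same adjusted over the list alone (0.398), interferon genes 2 up and 1 down of 12, the same adjusted over the list alone (0.607), and epithelial to mesenchymal transition genes 2 and 2 of 13, the same adjusted over the list alone (0.848). Cytosolic ribosomal protein genes had 2 up and 1 down of 21 (1 and 1 adjusted over the list alone, list 0.313), and microRNA machinery 1 up of 10, DICER1 (0 adjusted over the list alone, list 0.675).

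Markers of other cell types were tested as lists too. Adipocyte markers had 1 rise, CIDEC, and 2 falls of 6 genes (the same adjusted over the list alone, list adjusted p = 0.405), with PNPLA2 at -0.08. Fibroblast markers had 1 rise of 4 (2 adjusted over the list alone, list adjusted p = 0.0894), macrophage markers 0 of 4 (0 adjusted over the list alone, list 0.848), and mesothelial and alveolar type II markers 1 fall each, of 4 and 3 genes (1 each adjusted over the list alone, lists 0.675 and 0.835). In the mesothelial, alveolar type II and epithelial to mesenchymal transition lists the median slope was above 0 and the mean and the test below 0. Lymphocyte, endothelial and erythrocyte markers had fewer than 3 measured genes and were not tested. Of the 28 lists tested, 12 were called with the preset correlation and 0 with an estimated correlation, and 16 moved on balance to 1 side in fry. Permuting the doses within each series called a median of 4 lists over 100 draws, so calls with the preset correlation are liberal.

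At the top dose against control cells, the question was what 10.56 µg/ml of exosomes changed. CYP1B1 was 10.9-fold the control signal (log2 difference 3.45 ± 0.35 SE, adjusted p = 5.11e-05). CYP1A1, the other inducible P450 of the aryl hydrocarbon receptor, was not detected in control cells and was at least 3.79-fold higher, and TIPARP, a repressor of that receptor, was 5.15-fold the control (log2 difference 2.36 ± 0.27 SE). HMOX1 was higher by 1.78 ± 0.24, INSIG1 by 1.79 ± 0.33 and MSMO1 by 1.63 ± 0.38 (log2, SE). TXNIP had a log2 difference of -2.59 ± 0.38 (SE), so that control cells had 6.02-fold its signal, and the secreted pentraxin NPTX1 one of -2.08 ± 0.26 (SE). CXCL5 was at -1.71, CCN2 at -1.64, ANXA3 and DUSP1 at -1.46, DUSP5 at -1.45, the cytokine IL11 at -1.38, the kinase SIK1 at -1.37 and the scaffold NEDD9 at -1.35.

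Further genes higher at dose 10 were FXYD2 (log2 difference 2.08 ± 0.33 SE), RRAGD, a GTPase of amino acid sensing (1.59 ± 0.26 SE), RAB17 (at least 4.76-fold) and FGFBP1 (at least 2.21-fold). RAB17 rested mostly on series 2, with a log2 signal of 6.83 ± 2.61 (SD, n = 2). AXIN2 was 1.95-fold the control (adjusted p = 0.000268), PLIN2, a lipid droplet coat protein, 1.84-fold (adjusted p = 0.00092) and TGFBR3 1.63-fold (adjusted p = 0.0283), and FZD8 differed by -0.75 ± 0.11 (SE). ACVR2A differed by -0.06 ± 0.18 (SE, adjusted p = 0.928), TGFBR2 by -0.35 ± 0.19 (SE, 0.346) and CTNNB1 by 0.10 ± 0.18 (SE, 0.843). These values come from the limma fit without the series number as a block, so they are weak evidence for no change.

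In all, 547 genes passed at dose 10, 288 higher and 259 lower, and 1061 with the series number as a block (555 and 506). The count was 88 without series 2 of dose 10, 91 without series 2 of the control, 148 without series 1 of the control and 1057 without series 1 of dose 10, with the lone array assumed to vary like the other groups. From the authors' normalized table, dose 10 versus control gave 244 genes, and from the 4 arrays alone 2.

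By list at dose 10, cholesterol synthesis genes were higher in 10 of 14 cases and fatty acid synthesis genes in 7 of 11 (12 and 9 adjusted over the list alone). The mitosis genes CCNB2, CDC20 and UBE2C were lower, 3 of 18 in that list (7 adjusted over the list alone), with CCNB2, cyclin B2, at -0.69 ± 0.16 (SE). HSPA5 at -1.04 ± 0.17 (SE) and DNAJB9 were lower in the endoplasmic reticulum stress list of 16 (2 adjusted over the list alone). Of 18 TGF-beta targets 4 were lower (6 lower and 1 higher adjusted over the list alone), and 3 of 15 vesicle genes were higher (5 adjusted over the list alone). Of 17 NRF2 targets 2 were higher (4 higher and 1 lower adjusted over the list alone) and of 7 metallothionein list genes 1 (1). Of 11 heat shock, 19 oxidative phosphorylation and 17 S phase genes 0 passed (6, 0 and 0 adjusted over the list alone), though these lists were called higher. With the preset correlation, 11 of 28 lists were called, 8 higher and 3 lower, a comparison added after the data were seen. With an estimated correlation 0 were called, and the lowest adjusted p was 0.136. In the mesothelial, alveolar type II and interferon lists the median was above 0 and the mean and the test below 0.

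All exposed cells together were set against the controls to ask for a change shared by the doses. The smallest p-values belonged to FMC1, FN1, TARDBP, WHAMM and RNY5 among genes with a higher mean, and to VENTXP1, ASPH, GOLT1B, MOS and SBF1P1 among those with a lower mean. None passed: ASPH differed by -0.42 ± 0.12 (SE) and WHAMM by 0.37 ± 0.15 (SE), each with an adjusted p = 1.00. ACVR2A differed by -0.06 ± 0.12 (SE) and AXIN2 by 0.44 ± 0.29 (SE). In limma 0 genes passed, 127 had an unadjusted p under 0.05, and with the series number as a block 0 passed and 172 did. This fit has no term for the dose, so differences between the doses enter its spread and widen its SE. Its lack of calls is therefore weak evidence against a change shared by the doses. As groups, 8 lists were called with the preset correlation, 7 higher, led by S phase genes (median 0.33, adjusted p = 2.87e-05) and cholesterol synthesis (median 0.48, 0.000115), and 1 lower, the endoplasmic reticulum stress list (median -0.49, 0.00018), while 0 member genes passed and 0 when adjusted over the list alone. With an estimated correlation 0 lists were called (lowest adjusted p = 0.564), fry called 0, and 5 were called without series 1 of the control. In the alveolar type II list the median was below 0 and the mean and the test above 0, and in the ribosomal protein list the test alone was above 0.

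A test for any difference between a dose and the control asked for responses of every shape. It called 1409 genes, 12.4% of those tested, and 2540 with the series number as a block. For any dose difference the count was 647 from the authors' normalized table and 934 without series 2 of dose 8.

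The series were compared within doses, since each had its own control. Series 2 was higher in HSPA1A by 0.81 ± 0.14 (log2, SE, 11 pairs, adjusted p = 0.000561) and in PERP, a desmosome protein, by 0.73 ± 0.06. The 28S ribosomal RNA gene RNA28SN5 was higher by 1.71 ± 0.34 and the pseudogene TPI1P2 by 0.70 ± 0.07. PLPP2 was higher by 0.71 ± 0.08, with neither of its 2 other probes of that sign. NIBAN1 differed by -0.51 ± 0.17, NTN4, a netrin, by -0.51 ± 0.08, MYL12A, a myosin light chain, by -0.50 ± 0.05, TNFRSF12A by -0.50 ± 0.12 and COL8A2, a collagen chain, by -0.49 ± 0.06. In all, 2496 genes differed, 1029 higher and 1467 lower in series 2, and 1298 without the dose as a block.

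Whether the slopes differ between the series was tested gene by gene and by list. Fatty acid synthesis genes had more positive slopes in series 2 in 11 of 11 cases, with a median difference of 0.05 per doubling, and cholesterol synthesis genes in 13 of 14, with a median of 0.08. Heat shock genes had them in 10 of 11 cases and NRF2 targets in 13 of 17, while all 18 mitosis genes and 14 of 16 endoplasmic reticulum stress genes had lower slopes. In limma 0 genes passed and 788 had an unadjusted p under 0.05 (smallest adjusted p = 0.141), and adjusted over the list alone 2, 1, 1, 0, 0 and 0 genes of these lists passed. With the preset correlation 6 lists were called, and with an estimated correlation 0 (lowest adjusted p = 0.236). Median, mean and test differed in sign in the mesothelial, macrophage, epithelial to mesenchymal transition and NF-kappaB lists, none of them called.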

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

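The test of a response that starts 1 dose step later in series 1 was chosen only after the result was seen.

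In 6 gene lists the slope on dose differed between the series in camera with a preset correlation. Upward slopes were steeper in series 2 for fatty acid synthesis (adjusted p = 4.08e-06, median difference 0.05 per doubling), cholesterol synthesis (7.81e-06), heat shock (0.000411) and NRF2 targets (0.0363), and slopes were lower for mitosis (0.00762) and for the endoplasmic reticulum stress and amino acid response (0.0365). With an estimated correlation none of the 6 passed, with adjusted p = 0.236 for fatty acid synthesis and NRF2 targets.

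Swapping the series number within doses called at least 6 lists in 23 of 100 draws, with up to 9 lists, so chance cannot be excluded for these differences. For single genes the real count was 0, so every draw of the 100 gave as many by construction, and what set apart the highest, with 591 genes, was not tested. Without the dose 10 arrays, 4 lists still differed (fatty acid synthesis, cholesterol synthesis, heat shock and NRF2 targets), so with the preset correlation the dose 10 array of series 1 alone does not account for those, though their adjusted p was 0.0222, 0.0427, 0.0222 and 0.0222, and with an estimated correlation none passed (lowest 0.362). A response that starts 1 dose step later in series 1 was tried as an explanation. Over 85 genes of the called lists, picked for their difference, a shift by 1 step brought the mean squared distance between the series to 0.403 of that without a shift. It was 1.78 with a shift the other way, and over the 3171 dose trend genes these were 0.752 and 1.34. A later start did not hold for every list. At dose 6 the median difference from control in series 1 and 2 was 0.31 and 0.36 for fatty acid synthesis, against -0.05 and -0.38 for endoplasmic reticulum stress. The gap was large at dose 7, with -0.21 and -1.23 for endoplasmic reticulum stress and 0.10 and 0.86 for heat shock. Each of these rests on 1 array per series, the ratios were not computed without dose 7, and chance stays open here too. Donor, vesicle preparation, culture and array batch stay open, since the labels separate none of them.

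Among 4821 detected probes without a gene name, which the comparisons leave out, 537 had a slope on dose, 240 upward and 297 downward, or 11.1% of them.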

How the results depend on the processing

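The settings without dose 10, with doses 1 to 6, with detected probes as a covariate, a background correction of the authors' normalized table, and the lists at dose 10 were chosen only after the data were seen. Of 15545 values of single genes and lists under alternatives, 14560 kept their direction and side of the threshold, 660 lost a call, 129 gained 1, 183 changed sign without a call and 13 reversed. Many of these values had no call to lose. Genes of exposed versus control, where 0 were called, supplied 3810 values, of which 3772 stayed the same. Of the lost calls, 298 were genes of the dose trend and 262 genes of dose 10 versus control. The cause of the changes below was not tested. The dose trend gave 581 genes with series 1 alone, against 2798 with series 2 alone, and 0 with doses 1 to 6, and dose 10 versus control gave 2 with only its 4 arrays. With log2 of the authors' normalized table, dose 10 versus control gave 244 genes, any dose difference 647, series 2 versus series 1 5206 and dose trend difference between series 2. With the replicate block, dose 10 versus control gave 1061 and any dose difference 2540, and the block changed no other count of the fixed comparisons by more than 1.5 times. The mean of doses 9 and 10 against control gave 960, series 2 versus series 1 with no block by dose group 1298, and dose trend difference between series with all probes 1. For the gene lists, an estimated inter-gene correlation gave 0 for the dose trend, 0 for exposed versus control and 0 for dose 10 versus control, for exposed versus control fry gave 0 and the authors' normalized table gave 4, and doses 1 to 6 only 6 for the dose trend. With 1 array left out, the dose trend ranged from 2729 to 3597, exposed versus control stayed at 0, and series 2 versus series 1 ranged from 2111 to 2390. Dose 10 versus control ranged from 88 (without dose 10 replicate 2) to 1057 (without dose 10 replicate 1), with 91 and 148 without control replicate 2 and 1. Any dose difference ranged from 934 (without dose 8 replicate 2) to 1939, and dose trend difference between series from 0 to 1 (without dose 10 replicate 1). Gene lists ranged from 11 to 13 for the dose trend, from 5 (without control replicate 1) to 9 for exposed versus control, and from 6 (without dose 10 replicate 2) to 11 for dose 10 versus control. With all probes, CD68 reversed to -0.052 for the dose trend and -0.68 for dose 10 versus control, and PLPP2 to -0.047 for series 2 versus series 1. With doses 1 to 6 only, the slope reversed for ANGPTL4 (0.045), CCN1 (0.0067), CFD (0.0031), DICER1 (-0.028), HSPA1A (-0.0021), IFIT3 (-0.0076), LRP5 (-0.00089), PNPLA2 (0.027) and RPS23 (-0.021), and the TGF-beta target list turned upward (adjusted p = 0.725). A chip block was not run, since no chip numbers are given. Genes near the background on all arrays, such as ACVR2B, cannot be judged.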

Other observations

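The comparison of dose 10 with doses 8 and 9 and the tests of its explanations were chosen only after the result was seen.

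Between doses 8 and 9 and dose 10 the signal changed for several groups of genes. Some, such as STC2 and DDIT3, went back toward the control, while CYP1B1 and NPTX1 moved further from it. STC2, a secreted glycoprotein, was higher at dose 10 by 2.71 ± 0.60 (log2, SE, adjusted p = 0.0102), DDIT3 by 2.21 ± 0.45, CYP1B1 by 2.13 ± 0.30, ATF3 by 1.99 ± 0.39 and NUPR1, a stress-induced nuclear protein, by 1.89 ± 0.22. NPTX1 had a difference of -1.59 ± 0.23, POLE2, a subunit of DNA polymerase epsilon, -1.36 ± 0.15, NR4A2, an orphan nuclear receptor, -1.33 ± 0.13, MCM4 -1.18 ± 0.16 and GINS2 -1.17 ± 0.12. In all, 638 genes differed, 244 higher and 394 lower, and 1081 with the series number as a block. For dose 10 versus doses 8 and 9 the count was 279 with log2 of the authors' normalized table, 337 without dose 9 replicate 1 and 424 without dose 10 replicate 2.

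None of the 17 S phase genes and none of the 18 mitosis genes was higher at dose 10 in either series. Their median log2 differences were -0.74 and -0.77 for S phase and -0.55 and -0.89 for mitosis in series 1 and 2. With the preset correlation the lists had adjusted p = 3.26e-19 and 8.02e-19, with an adjusted p = 0.0405 and 0.0606 with an estimated correlation. Of 16 genes of the endoplasmic reticulum stress and amino acid response, 14 were higher in each series, with medians of 1.17 and 0.49 (adjusted p = 1.26e-09, with an adjusted p = 0.499 with an estimated correlation). Immediate early genes were higher, with medians of 0.69 and 0.12 (adjusted p = 0.0013), and heat shock genes lower, with medians of -0.62 and -0.11 (adjusted p = 0.00218), each with an adjusted p = 0.575 with an estimated correlation. Cholesterol synthesis genes differed between the series at this step, untested, with medians of -0.50 (1 of 14 higher) and 0.33 (13 of 14 higher), as did fatty acid synthesis genes, with medians of -0.21 and 0.32, and neither list was called over both series (adjusted p = 0.702 and 0.589).

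For the return of the amino acid response genes at dose 10, a dose 10 array of series 1 that holds cells of a low dose was tested. The test used 11 genes more than 1 log2 unit higher at dose 10 in series 2 than the mean of doses 8 and 9 and than every dose from 1 to 6. That filter leaves out STC2, DDIT3 and NUPR1, and the amino acid response list has no member among the 11. On the series 1 array 90.9% of the 11 (95% exact interval 58.7 to 99.8) lay above doses 1 to 6, against 19.4% of other genes. CYP1B1, CYP1A1 and TIPARP, all tied to the aryl hydrocarbon receptor, were among them. Without the filter on doses 1 to 6 the share was 70.8% of 24 genes (48.9 to 87.4). These shares argue against a low-dose array only as far as the genes are independent, which the intervals assume, and all were read on 1 array. RNA like that of doses 8 and 9 mixed with RNA of unexposed cells was not decided by these genes, of which 72.7% (39.03 to 93.98, other genes 39.5%) were higher than at both doses 8 and 9 in series 1, nor by the mitosis genes, of which 55.6% (30.8 to 78.5, other genes 26.99%) lay below the control and both doses, all 18 of which were already known to lie below the mean of these doses. A further test, added after these were undecided, argues against it as far as the genes are independent: a mixture cannot exceed its highest source, yet the 11 genes exceeded the highest of control and doses 8 and 9 in series 1 by a median of 0.35, against 0.16 in the highest of 10000 random lists and 0.24 with lists matched on level and spread, and the 24 genes by 0.30, against 0.06 with matched lists. The list rose in series 2 too, by a median of 0.49, above all 10000 random lists. It was picked after its return was seen, and random lists lack the correlation between its genes. With an estimated correlation the camera adjusted p over both series was 0.499. The random lists thus cannot decide whether a change that both series share accounts for part of the pattern. RNA of a stronger response mixed with that of unexposed cells stays open, each series has 1 array per dose, and toxicity at the top dose was not tested.

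For the genes with a dose trend, the array background was tested as a source, with the array median in the authors' normalized table as its measure, although the fits used the quantile normalised table, where medians are alike. The correlation of this median with dose was r = 0.457 in series 2 (rho = 0.503, permutation p = 0.184, adjusted over 9 relations 0.827), -0.0996 in series 1 and 0.216 over both. Of the genes called in series 2, 95.96% had the same sign of slope in series 1, against 95.82% in the highest of 100 draws with permuted doses, while the correlation of slopes across genes was 0.803, against 0.811 in the highest draw, so this test does not exclude the background. Series 1 alone called 581 genes. Without the 2 farthest arrays, the correlation of this median with dose was -0.430 in series 1 and 0.569 in series 2. With 10 arrays per series, the lack of a clear correlation in series 1 does not clear the 581 genes, and the background stays open for all. Permuting the doses within the series gave as many as 3171 genes in 1 of 100 draws, the real one, with 729 in the highest other. A chance order of the doses is thus unlikely, at a level of 1 in 100, the lowest these draws can reach. The draws do not bear on causes that run along with the dose. For the lists with a dose trend, 2 of 100 draws gave as many as 12, the real one included, and the highest other gave 12. For the genes that differ between the series, 1 of 100 draws gave as many as 2496, with 0 in the highest other.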
